A study of Mus musculus with 13 samples.

How the data were processed

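Mouse embryonic stem cells (ESCs) of a male line from a cross of the CAST and B6 strains were profiled by ChIP-seq. The line carries a recombination cassette at Rosa26, a locus on chromosome 6 that is often used for transgenes. Per the labels' protocols, all cells had 3 days of doxycycline and were crosslinked in 0.6% formaldehyde. The 13 libraries fall into 4 groups by genotype and antibody. There were 5 WT and 4 SAFB and SAFB2 double knockout (DKO) libraries for H3K27me3, and 2 WT and 2 DKO libraries for total H3. Per the labels, DKO replicate 1 for H3K27me3 came from clone 4 and all other DKO libraries from clone 13. The labels of 4 of the H3K27me3 libraries carry the word Old (WT replicate 4, DKO replicate 3) or New (WT replicate 5, DKO replicate 4). The other 5 carry neither. What these words mean is not given in the sources used here, and they were treated as library sets. The term for the library sets kept Old, New and neither apart, while fits within the libraries with Old or New pooled both. The library names in the labels of WT replicates 1, 4 and 5 share a stem, while those of WT replicates 2 and 3 have other stems. Whether these are separate WT clones is not given in the sources used here, so the spread between WT libraries may hold differences between clones. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

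The deposited tables hold raw read counts with no normalization. Per the file headers, the authors made the promoter counts with featureCounts 2.0.3 without regard to strand and without the option that assigns a read to several rows, so a read that overlapped more than 1 promoter row was not counted. Bowtie2, MACS2, bedtools, Subread and featureCounts are named in the submitters' processing notes without roles, with genome build mm10. Column names carry the tag b6, and whether reads of both parental alleles were counted is not given in the sources used here. A promoter row spans 3001 bp, from 2000 bp upstream to 1000 bp downstream of a start site. Of the 77489 rows used, 12386 had no base of their own and 36042 were free of overlap, so a low count can come from overlap with a neighbouring row and not from a low signal. The Gm21748 row spans 90841178 bp of chromosome Y and took its reads. It was left out with 37 rows of chromosome M, and the remaining 1712 rows of chromosome Y held 0 reads. Chromosome shares were therefore compared over 20 chromosomes, without chromosome Y, although it had been meant to enter. Symbols of 38980 of the 55232 genes matched the RefSeq table of assembly GRCm38.p6, which was used for the genes at a region and not for exon or intron positions.

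The deposited region tables for the WT, DKO and H3 libraries hold raw counts over the same 57909 regions, a union of both genotypes. A separate table of regions per genotype had been assumed. Because the rows were identical, the WT and DKO columns were fitted together, WT-called regions were taken as the authors' shared and WT-specific lists, and DKO-called regions as the shared and DKO-specific lists. The deposited lists give coordinates, lengths and names without a score. How the regions were called, and whether on pooled libraries, is not given in the sources used here. A region called in 1 genotype alone is lower in the other by selection.

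Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, two-sided, with no covariate. Rows were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the root of F. Levels are counts per library scaled by TMM, as CPM. Fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with 1 row per gene, and again with an estimated correlation and with fry. Chromosome shares were compared by exact permutation of the 9 libraries over 126 groupings, two-sided. DESeq2 1.42.0 was an alternative test. Shares and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

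The tests were checked on simulated counts with 200 changed rows. For promoters (31163 rows run), 11.9% of rows changed by 1.5-fold, 61.2% of those changed by 2-fold and 87.9% of those changed by 3-fold were recovered, and 7% of all calls were false. For regions (37816 rows run) the shares were 34.3%, 65.7% and 84.8%, with 7.5% of calls false. For total H3 (17152 rows run) they were 3%, 28.4% and 68.2%, with 5.7% of calls false. DESeq2 recovered 3%, 34.3% and 78.8% on the promoters (32647 rows run), with 0% of calls false. In simulated promoters with 1 list of 30 genes lowered by 1.3-fold, camera called that list and 0 of 13 unchanged lists at either correlation. The simulated rows varied independently of each other. In the data the estimated correlation was 0.257 for the Hox, 0.228 for the neural, 0.194 for the mesoderm and endoderm and 0.199 for the signalling list. The simulation therefore cannot show how the preset correlation of 0.01 performs for such lists. All pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.06 to 2.18. Technical libraries can differ in this way too, so this does not show separate cultures. Each library was counted as 1 replicate.

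Before the data were examined, the tests, the gene lists, the main alternatives and the rule for named genes were fixed. The rule took, among promoter rows past the threshold and with 1 row per gene (the smallest p), the 8 largest rises and the 8 largest falls. Symbols that are only a clone or model name (Gm with digits, ending in Rik, or LOC, BC or AK names) were left out. It added the 2 members of smallest p of each of 14 lists, and always Safb, Safb2, Hoxb1, Hoxc4 and Hoxd13. Some items that the rule took, or that passed, are not reported here. Of regions it took the 5 largest rises and the 5 largest falls past the threshold. All other genes and regions were chosen after their values were seen, as the text says beside them. The alternatives fixed then covered scaling, filters, the test, the replicate block, the library sets, the clones, the rows tested and leaving out each library. The comparisons of the longest regions and of chromosome 11, the offsets for chromosome 11 and for signal level, the fits within library sets, the promoters off chromosome 11, the scaling off chromosomes 6 and 11, the filtered rows with the scaling over all rows kept, the fits with WT replicates 1, 4 and 5 as the only WT libraries, the splits over shared regions alone, the shares in union regions and with chromosome 11 out of the denominator, the chromosome 17 share without the CT010467 rows, the fits to 1 set of called regions, fry and the fit relative to total H3 were added after seeing the data. The chromosome 11 offset scaled its rows in each library by their level in promoter rows without a region, and the level offset was a loess curve of each library against the mean with a span of 0.3.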

Results

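The series concerns SAFB and its paralog SAFB2, nuclear proteins that bind RNA, and their part in gene expression in mouse ESCs. Its ChIP-seq libraries measured H3K27me3, the histone mark laid down by Polycomb repressive complex 2, in WT and DKO cells, with total H3 as the background. Promoter rows held between 798466 and 1427771 counts per H3K27me3 library. The regions held between 1818647 and 3134799 counts per H3K27me3 library and between 525847 and 736566 per H3 library. The targeted genes could not check the genotype labels. The Safb and Safb2 promoter rows overlap, and over the 9 H3K27me3 libraries together Safb held 4 and 0 counts in its rows and Safb2 held 3.

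One comparison asked which promoters differ in H3K27me3 between DKO and WT. The promoter of Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 13.4 ± 5.78 CPM (SD, n = 5) in WT to 35.6 ± 9.19 CPM (SD, n = 4) in DKO. Its row lies on chromosome 14 from 105895819 to 105898819, and its log2 fold change was 1.47 with SE 0.23 (edgeR adjusted p of 3.15e-06). The promoter of Dusp6, a phosphatase that inactivates ERK (chromosome 10, 99261231 to 99264231), rose from 21.7 ± 6.10 CPM (SD, n = 5) to 50.4 ± 12.4 CPM (SD, n = 4). Its log2 fold change was 1.20 with SE 0.20 (edgeR adjusted p of 2.16e-05). The other 6 of the largest rises, on the log2 scale, were Mir3065 at 1.25, Arid3b at 1.16, AC163703.1 at 1.16, Gfpt2 at 1.14, Diras1 at 1.13 and Vpreb3 at 1.10. Gfpt2, an enzyme of the hexosamine pathway, and Mir3065 lie on chromosome 11. All 4 DKO libraries lay above every WT library at these promoters, except that 3 of 4 did at Spry2. Of 126 groupings 1 gives this for a row picked without its values, and picking the largest rises favours it. Within the libraries without and with Old or New in the label, Spry2 stood at 1.05 (not passing) and 1.89, and Dusp6 at 1.52 and 0.90 (not passing). In the same order Arid3b stood at 0.93 (not passing) and 1.52, AC163703.1 at 1.60 and 0.72 (not passing), Gfpt2 at 1.08 (not passing) and 1.25 and Mir3065 at 0.68 (not passing) and 1.74. Leaving out 1 library ended the call of Mir3065 (1.03 without WT replicate 5, 1.12 without DKO replicate 3), as did the chromosome 11 offset (0.95). It ended that of Diras1 without WT replicate 3, 4 or 5 or DKO replicate 2 or 4 (1.01 to 1.12), and that of Vpreb3 without WT replicate 4 or 5 or DKO replicate 1, 2 or 3 (0.93 to 1.11).

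The fall of smallest p was at CT010467.1 on chromosome 17 (39844353 to 39847353), where RefSeq places Rn18s-rs5, a sequence related to 18S ribosomal RNA. It fell from 5827 ± 1613 CPM (SD, n = 5) to 2651 ± 606 CPM (SD, n = 4), a log2 fold change of -1.14 with SE 0.09 (edgeR adjusted p of 4.04e-24). The neighbouring row CT010467.2 went from 1707 ± 321 CPM (SD, n = 5) to 789.5 ± 212 CPM (SD, n = 4), at -1.12. Ribosomal sequence has many copies, and reads from other copies can be placed here, so both values are uncertain. CT010467.1 stood at -0.96 and -1.32 within the libraries without and with Old or New in the label and CT010467.2 at -0.87 and -1.39, and all 4 values passed. The other 6 falls were at rows of low count: Sfta3-ps at -1.32, the olfactory receptor Olfr1406 at -1.22, Pnma5 at -1.14, the fatty acid desaturase Fads2 at -1.12, Wipf3 at -1.03 and the olfactory receptor Olfr46 at -1.02. Olfr1406, Pnma5, Fads2 and Olfr46 overlapped no H3K27me3 region. All 4 DKO libraries lay below every WT library at these falls, except 2 of 4 at Sfta3-ps and 1 of 4 at Olfr1406. Calls ended without DKO replicate 1, 2 or 3 for Sfta3-ps (-1.44 to -1.21), which was too low to be tested without WT replicate 1, 2, 3 or 5, without DKO replicate 2 or WT replicate 4 for Olfr1406 (-1.13 and -1.01) and without WT replicate 2 or DKO replicate 3 for Fads2 (-0.94 and -1.003). They also ended for Wipf3 without WT replicate 5 or DKO replicate 2, 3 or 4 (-1.03 to -0.91). Pnma5 lost its call without WT replicate 1, 2 or 3 or DKO replicate 2, 3 or 4 (-1.23 to -0.98), and Olfr46 without any 1 library except WT replicate 3 and DKO replicate 2 (-1.07 to -0.84). Their calls also ended with the chromosome 11 offset, at -1.14 and -1.02.

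By edgeR, 143 promoter rows rose and 62 fell of 32647 tested, at 141 and 61 genes. Chromosome 11 held 84 of the rises, 58.7% of them against 6.28% of the tested rows, and 0 of its 2051 rows fell (672 had an unadjusted p under 0.05). Among the 980 rows in the top 3% by level, 9 rose and 35 fell, with a median log2 fold change of -0.10. DESeq2 called 155 rows. The balance turned with the rows used: over the 9180 rows with a region alone 224 rose and 276 fell, and over the 3822 rows past a strict filter 190 rose and 208 fell. With the scaling over all rows kept, these were 227 rises and 105 falls, and 132 and 118. With no filter 115 rose and 19 fell, and with a term for the library sets 255 rose and 134 fell, with all 205 calls kept. With an offset for the level of chromosome 11 in each library 47 rows rose and 53 fell, with that and the level offset 68 and 32, and in a fit without its rows 48 and 30. There were 11 rises and 11 falls within the libraries without Old or New in the label, and 50 rises and 7 falls within those with it. With WT replicates 1, 4 and 5 as the only WT libraries 79 rose and 11 fell, and without WT replicate 4 alone 88 rose and 80 fell. The total of 205 dropped to 105 without WT replicate 2, 81 without WT replicate 5, 50 without DKO replicate 2 and 87 without DKO replicate 3.

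**Figure D1:**
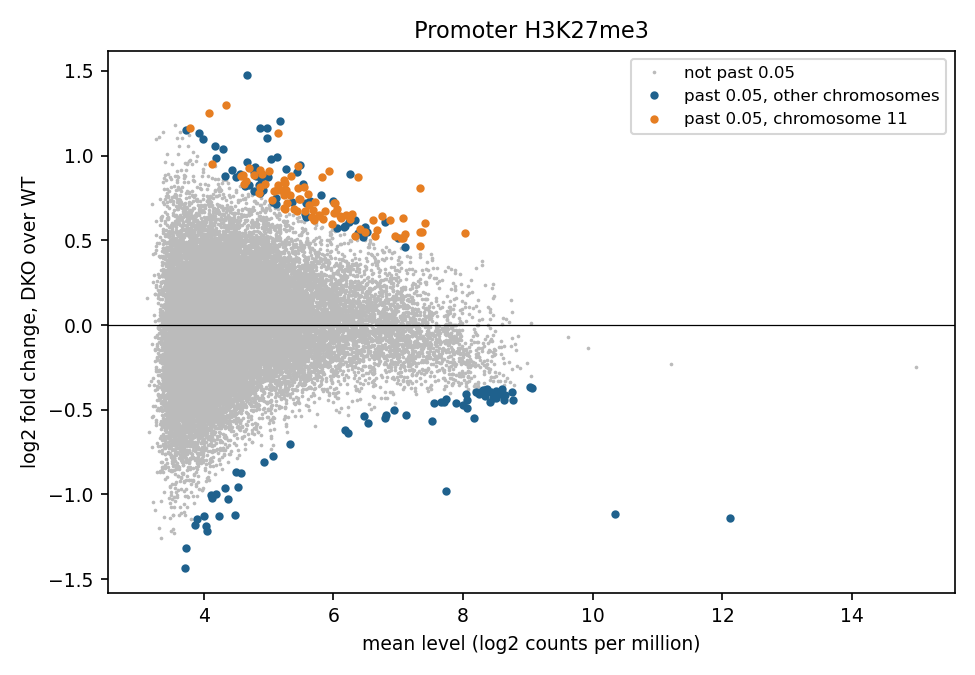
Log2 fold change of promoter H3K27me3 (DKO over WT) against mean level in log2 CPM, 1 point per tested promoter row. Of the 205 rows past an adjusted p of 0.05, the 84 on chromosome 11 all rose, while 35 of the 44 called rows in the top 3% by level fell.

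Among the fixed gene lists, the homeotic Hox genes lay lower as a list by camera, with an adjusted p of 5.95e-09 at the preset correlation and an adjusted p = 0.339 with an estimated correlation. The list's median was -0.24. Of 36 tested members 2 fell and 0 rose, and 15 were lower and 0 higher when adjusted over the list alone. Hoxd10, a regulator of limb and spinal patterning (chromosome 2, 74689924 to 74692924), fell by 0.45 on the log2 scale, from 451 ± 36.9 CPM (SD, n = 5) to 331 ± 12.4 CPM (SD, n = 4), and its neighbour Hoxd11 fell by 0.50. Hoxd10 stood at -0.42 and -0.44 within the libraries without and with Old or New in the label, not passing in either, and the lists were not tested within these sets. The list's median was negative under every alternative run, from -0.30 to -0.14. Its members stood at a median level of 276 CPM, and rows in the top 3% by level fell more often than they rose. With the level offset the list's median was -0.14 and its camera adjusted p 0.00516 at the preset correlation. Of the reference promoters Hoxd13 stood at -0.24, Hoxc4 at -0.16 and Hoxb1, on chromosome 11, at 0.23, and none of them passed. Hoxb1 turned to -0.063 with the chromosome 11 offset and passed at 0.34 with the level offset, and Hoxc4 stood at 0.034 within the libraries with Old or New in the label. The call of Hoxd10 ended without WT replicate 2 (-0.40), and that of Hoxd11 without any 1 library except WT replicate 4 and DKO replicate 1 (-0.56 to -0.39).

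The list of neural regulators had 38 tested members, of which 3 fell and 0 rose, and 11 were lower and 0 higher when adjusted over the list alone. Nkx2-1, a transcription factor of forebrain, thyroid and lung, fell by 0.57 on the log2 scale, from 214 ± 19.5 CPM (SD, n = 5) to 144 ± 8.69 CPM (SD, n = 4). It stood at -0.57 and -0.52 within the libraries without and with Old or New in the label, not passing in either. Dbx1, a spinal cord patterning factor, fell by 0.40, a call that ended without any 1 library except WT replicate 4 and DKO replicate 4 (-0.42 to -0.34) and with the offset for chromosome 11 (-0.40) or for level (-0.28). The list's median was -0.20, with an adjusted p of 4.02e-11 at the preset correlation and an adjusted p = 0.339 with an estimated correlation. Its median level was 200 CPM. With the level offset its median was -0.14 and its camera adjusted p 2.22e-06 at the preset correlation.

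Of 37 tested mesoderm and endoderm regulators 0 passed over all rows by edgeR (10 had an unadjusted p under 0.05), and 8 were lower and 0 higher when adjusted over the list alone. The endoderm factor Foxa2 stood at -0.50 (it passed without WT replicate 1, at -0.52, or WT replicate 4, at -0.55). The list's adjusted p was 6.67e-05 at the preset correlation, and the adjusted p = 0.339 with an estimated correlation. With the level offset the list's median went from -0.13 to -0.064, and its camera adjusted p was 0.0213 at the preset correlation. Of 42 tested signalling ligands and receptors 1 fell and 0 rose, with 2 higher and 3 lower when adjusted over the list alone. The Notch ligand Dll4 fell by 0.46, a call that ended without any 1 library except WT replicates 1 and 4 and DKO replicate 1 (-0.50 to -0.39). The Hedgehog receptor Ptch1 stood at 0.84 (it passed without DKO replicate 1, at 0.97). The list's adjusted p was 0.0255 at the preset correlation, and the adjusted p = 0.458 with an estimated correlation. Its call ended with the level offset (adjusted p = 0.332), with WT replicates 1, 4 and 5 as the only WT libraries (adjusted p = 0.486) and without WT replicate 1, 2 or 3 or DKO replicate 3 or 4 (adjusted p of 0.105, 0.121, 0.0786, 0.273 and 0.119). Thus 4 lists were called at the preset correlation, against 0 with an estimated correlation (1 unadjusted p under 0.05) and 0 by fry (4 under 0.05). In 15 of 60 splits of the libraries, the true one included, at least 4 lists were called, so these list calls were not distinguished from other groupings of the libraries.

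The other 10 lists were not called by camera in the fit with all libraries and no covariate. Trophoblast genes were called without WT replicate 4 (adjusted p of 0.0287) and pluripotency genes without WT replicate 5 (adjusted p of 0.0426). Of 13 tested pluripotency genes 1 fell, the naive-state factor Klf2, by 0.81 on the log2 scale, from 36.5 ± 6.83 CPM (SD, n = 5) to 20.5 ± 6.90 CPM (SD, n = 4). Nr0b1 stood at -0.56, and 2 members were lower when adjusted over the list alone. Of 19 tested Polycomb genes 1 fell, over all rows and over the list alone: Bmi1, a subunit of Polycomb repressive complex 1, by 0.42, while Phc2 stood at 0.34. Of 4 tested genes of SAFB and nuclear speckle proteins 1 rose, over all rows and over the list alone: the RNA-binding protein Khdrbs1, at 0.61. The median of that list was -0.022 while its mean was 0.11. Thoc1 stood at -0.13, turning to 0.0042 without WT replicate 4 and 0.034 without DKO replicate 3. Of 29 tested migration and adhesion genes 1 rose, the receptor tyrosine kinase Epha2, at 0.73, with 2 higher when adjusted over the list alone, and the integrin Itga5 stood at 0.62. Leaving out 1 library ended the calls of Klf2 (WT replicate 2, 3 or 5 or DKO replicate 2 or 3, -0.79 to -0.61), Bmi1 (WT replicate 2, 3 or 5 or DKO replicate 1 or 2, -0.42 to -0.38) and Khdrbs1 (0.55 without DKO replicate 2, 0.475 without WT replicate 4). The call of Epha2 ended without any 1 library except WT replicate 4 and DKO replicate 1 (0.63 to 0.78). Klf2 stood at -0.88 and -0.69 within the libraries without and with Old or New in the label and Epha2 at 1.12 and 0.41, none of these passing, Bmi1 at -0.50 (passing) and -0.32, and Khdrbs1 at 0.53 and 0.79 (passing).

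No member passed over all rows by edgeR in the remaining 6 lists, where 11 of 75 had an unadjusted p under 0.05. Among 25 tested imprinted genes Peg3 stood at 1.06 and Igf2 at -0.33, with 1 member higher when adjusted over the list alone. Peg3 passed without DKO replicate 1, at 1.36. The median of that list was -0.0064 and its mean 0.0064. Among 15 trophoblast genes Tfap2c stood at -0.34 and Gata2 at -0.26. Among 12 genes of the 2-cell stage and germline Tdpoz4 stood at -0.50 and Tex101 at 0.23. Among 11 genes of apoptosis and the p53 response Tnfrsf10b stood at -0.53 and Cdkn1a at -0.49. Among 10 fibroblast genes Col1a1 stood at 0.31 and Col6a1 at 0.44, with a list median of -0.0013 and a mean of 0.031. Of the 25 housekeeping genes only B2m, at -0.19, and Psmb2, at -0.32, had enough counts to be tested. The camera adjusted p of these lists ran from 0.122 for trophoblast genes to 0.727 for imprinted, 2-cell and fibroblast genes.

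Regions called in WT were compared next, with the limit that selection lowers the WT-specific ones in DKO. The largest falls lay within Cacna1c, a calcium channel gene, on chromosome 6 (118859032 to 118859601) at -1.97, Eps8 (137623571 to 137624167) at -1.78, Pde1c (56136621 to 56137239) at -1.75 and outside any named gene at 94478832 to 94479108 at -1.71, all on chromosome 6 and called in WT alone. A shared region within Gm30821 on chromosome 18 (68691902 to 68692358) stood at -1.70. The Cacna1c region fell from 5.47 ± 1.93 CPM (SD, n = 5) to 1.31 ± 0.585 CPM (SD, n = 4). All 4 DKO libraries lay below every WT library at these 5 regions. The Eps8 region lost its call without DKO replicate 3 (-1.46), and the last of the chromosome 6 regions without DKO replicate 2 (-1.45) or 4 (-1.57). The Cacna1c region was too low to be tested without any 1 WT library, and the Pde1c region and the last of the chromosome 6 regions without WT replicate 2, 3, 4 or 5. Within the libraries without Old or New in the label the Cacna1c region stood at -2.80 and passed, and it could not be tested within those with it. The Gm30821 region stood at -1.61 and -1.80 within these sets and passed in both. Over all regions tested, chromosome 6 held 16 rises and 314 falls of 15714, or 41.4% of the falls against 38.9% of the tested regions. Of 31977 WT-called regions tested by edgeR 416 rose and 757 fell, and among the 4504 WT-specific ones 0 rose and 258 fell (1828 had an unadjusted p under 0.05). DESeq2 called 657.

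The balance in WT-called regions moved with scaling. Library totals gave 739 rises and 460 falls, the fit to these regions alone 658 and 350, the level offset 532 and 427, the chromosome 11 offset 97 and 622, and scaling off chromosomes 6 and 11 gave 263 and 889. Within the libraries without Old or New in the label 17 rose and 119 fell, and within those with it 214 rose and 284 fell. With WT replicates 1, 4 and 5 as the only WT libraries 208 rose and 413 fell. The total of 1173 went to 2192 without WT replicate 1, 776 without WT replicate 2, 760 without WT replicate 4, 658 without WT replicate 5, 524 without DKO replicate 2 and 481 without DKO replicate 3.

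Regions called in DKO had their largest rises at short DKO-specific regions. One within Sdk2, a cell adhesion gene on chromosome 11 (113901826 to 113902322), rose from 1.35 ± 0.931 CPM (SD, n = 5) to 5.19 ± 0.582 CPM (SD, n = 4), at 2.06 on the log2 scale. The other 4 lay on chromosome 8 (121397959 to 121398296) at 1.75, on chromosome 11 (63955493 to 63956305) at 1.74, at the promoter of Tnfrsf19 on chromosome 14 (61038319 to 61038770) at 1.71 and within Rai1 on chromosome 11 (60145047 to 60145474) at 1.69. All 4 DKO libraries lay above every WT library at these 5 regions. The Rai1 region lost its call without DKO replicate 3 (1.63) and with the chromosome 11 offset (1.39), and the chromosome 8 region was too low to be tested without WT replicate 4 or 5 or DKO replicate 3 or 4. The Sdk2 region stood at 1.84 (not passing) and 2.42 within the libraries without and with Old or New in the label. Of 35914 DKO-called regions tested 872 rose and 500 fell. Chromosome 11 held 533 of the rises (61.1%), from 2699 of its regions tested. Among the 8441 DKO-specific regions 456 rose and 1 fell, a direction that selection favours. DESeq2 called 313 higher and 402 lower.

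The balance in DKO-called regions also moved with scaling. Library totals gave 1418 rises and 311 falls, the level offset 919 and 221, the fit to these regions alone 565 and 732, scaling off chromosomes 6 and 11 527 and 673, and the chromosome 11 offset 259 and 459. Within the libraries without Old or New in the label 27 rose and 114 fell, and within those with it 407 rose and 204 fell. With WT replicates 1, 4 and 5 as the only WT libraries 465 rose and 307 fell. The total of 1372 went to 2301 without WT replicate 1, 759 without WT replicate 5, 647 without DKO replicate 2 and 558 without DKO replicate 3. Tested relative to total H3, the shared CT010467.1 region on chromosome 17, at -0.76, was the only region to pass among WT-called or DKO-called regions (2438 and 2777 had an unadjusted p under 0.05). With that term the median was -0.135 over 37493 WT-called and 0.069 over 44917 DKO-called regions. Without it the median was -0.096 over 31977 and 0.033 over 35914. These medians cover different sets of regions. With no filter and without that term the median was -0.166 over 39072 WT-called and 0.103 over 47011 DKO-called regions. The medians therefore cannot show how far total H3 accounts for the changes, and the loss of calls does not show it either.

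The longest shared regions, chosen after their values were seen, were lower in DKO. Off chromosomes 6 and 11 there were 91 of at least 20 kb, of which 72 fell and 0 rose by edgeR (81 had an unadjusted p under 0.05), with a median log2 fold change of -0.29. DESeq2 called 71 of them lower. The HoxD cluster (chromosome 2, 74646526 to 74715895) fell from 3329 ± 71.6 CPM (SD, n = 5) to 2549 ± 101 CPM (SD, n = 4), at -0.39. The HoxC cluster (chromosome 15, 102921117 to 103045228) stood at -0.34 and, on chromosome 6, the HoxA cluster (52146181 to 52279242) at -0.37. The regions of the developmental transcription factors Otp, Hmx3, Pou3f2 and Pax2 stood at -0.42, -0.42, -0.41 and -0.39. All 4 DKO libraries lay below every WT library at each of these 7 regions, and each passed. The HoxB cluster on chromosome 11 (96249272 to 96377726) stood at -0.027 and did not pass, and it turned to 0.040 by library totals and 0.0049 without WT replicate 3. It passed at -0.32 with the chromosome 11 offset and, in the other direction, at 0.35 with the level offset. With the level offset 15 of the 91 fell and 5 rose, the median was -0.067, and the HoxA, HoxC and HoxD clusters stood at 0.0046, 0.022 and -0.063 and did not pass. Relative to total H3 the median was -0.27 (quartiles -0.34 and -0.18), against -0.29 (quartiles -0.35 and -0.20) without that term. The median SE went from 0.056 to 0.137, and 0 of the 91 passed by edgeR (46 had an unadjusted p under 0.05). Shared regions of 5 to 20 kb off chromosomes 6 and 11 held 24 rises and 238 falls of 1795, with a median of -0.098. The balance was the other way in those of 1 to 5 kb, with 101 rises and 69 falls of 9334 and a median of 0.024, while those under 1 kb held 1 rise and 15 falls of 4555. Within the libraries without and with Old or New in the label, 52 and 41 of the 91 fell, and the HoxD cluster stood at -0.36 and -0.41 and passed in both.

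Total H3 addressed whether the background differed between the genotypes. It fell by 0.50 on the log2 scale at the CT010467.1 region on chromosome 17 (39842973 to 39848922), from 2554 ± 472 CPM (SD, n = 2) to 1832 ± 639 CPM (SD, n = 2), by 2.40 at an Agfg2 region on chromosome 5 (137685384 to 137686617) and by 1.46 at a region of chromosome 6 (32259264 to 32262593). By edgeR 1 region rose and 3 fell of 18938 tested, while 1169 had an unadjusted p under 0.05, and DESeq2 called 0 (157 under 0.05). The median log2 fold change of H3 was 0.31 over chromosome 11 and -0.019 off chromosomes 6 and 11. The 4 calls became 2 with no filter, 0 without WT replicate 1 (1057 had an unadjusted p under 0.05), 1 without WT replicate 2 and 2 without DKO replicate 2, where the lone library is assumed to vary like the others. Without DKO replicate 1 there were 4 calls, 1 of them shared with the 4 calls from all libraries. The chromosome 17 region stood at -0.28 without WT replicate 1 and -0.14 without DKO replicate 2, not passing, and at -0.88 without DKO replicate 1. The Agfg2 region (-2.54 to -2.20) and the chromosome 6 region (-1.50 to -1.39) lost their calls without each of the 4 libraries in turn.

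Chromosome 6 carries Rosa26, so its share of promoter counts was compared. It was 9.42 ± 0.817% (SD, n = 5) in WT and 9.003 ± 0.440% (SD, n = 4) in DKO. The difference of -0.41 percentage points was within the spread between libraries (exact permutation test, p = 0.405, adjusted p = 0.623). It was -0.74 points over rows with a region alone and -1.63 points in union regions (exact permutation tests, adjusted p of 0.489 and 0.615). Over all promoter rows it was -0.22 points within the libraries without Old or New in the label and -0.75 points within those with it. WT replicate 1, at 8.11%, lay below all 4 DKO libraries, and without it the difference was -0.74 points (exact permutation test, adjusted p = 0.191). Without WT replicate 2 and WT replicate 5 it was -0.25 and -0.24 points. In union regions WT replicate 1 stood at 18.35%, the other WT libraries at 22.42% to 24.31% and the DKO libraries at 19.45% to 22.12%. Shared regions were looked at after these values were seen. On chromosome 6, 2 rose and 100 fell of 10280, with a median log2 fold change of -0.15. Off chromosomes 6 and 11, 126 rose and 394 fell of 15775, with a median of -0.0071.

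Of the other chromosomes, chromosome 11 stood apart and was chosen after its values were seen. Its share was 6.98 ± 0.233% (SD, n = 5) in WT and 8.50 ± 0.610% (SD, n = 4) in DKO, higher in 4 of 4 DKO libraries. The exact permutation p of 0.00794 is the smallest these groupings can give, and the adjusted p, over 20 chromosomes, was 0.0952. Over rows with a region alone the difference was 1.85 points (exact permutation test, adjusted p = 0.0397). The clone 4 library stood at 7.645% and the clone 13 libraries at 9.09%, 8.63% and 8.66%. The difference was 1.26 points within the libraries without Old or New in the label and 1.85 points within those with it. For total H3 the share was 8.09 ± 0.0289% (SD, n = 2) in WT and 9.97 ± 0.166% (SD, n = 2) in DKO, where the exact permutation p of 0.333 is the smallest that 6 groupings can give. For H3K27me3, both adjusted p-values of the chromosome 11 share rest in part on the small p of other chromosomes, with lower shares in DKO, in the same family (7, 14, 17 and X over all rows, and 2, 13 and 14 over rows with a region). The shares of a library add up to a whole, so a higher share of chromosome 11 lowers the others. With chromosome 11 left out of the total, the adjusted p of the other 19 chromosomes ran from 0.226 to 0.929 over all rows and from 0.151 to 0.651 over rows with a region (exact permutation tests). The unadjusted p was then under 0.05 for chromosomes 9, 10 and 17, and also for chromosome 12 over rows with a region. The chromosome 17 share went from 4.24 ± 0.219% (SD, n = 5) to 3.94 ± 0.0628% (SD, n = 4), with an adjusted p of 0.0952, or 0.271 with chromosome 11 left out of the total (exact permutation tests). Without the 2 CT010467 rows it was 3.58 ± 0.0586% (SD, n = 5) in WT and 3.63 ± 0.0233% (SD, n = 4) in DKO (exact permutation test, adjusted p = 0.423).

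**Figure D2:**
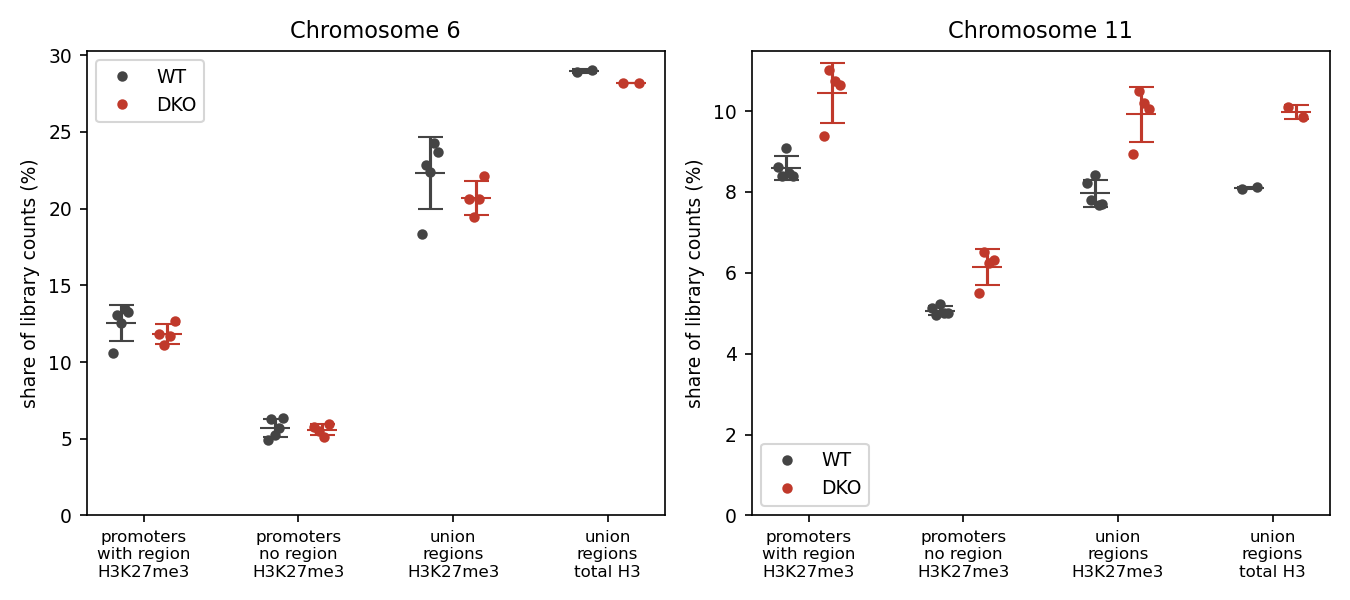
Share of each library's counts (%) on chromosomes 6 and 11 in promoter rows with and without a region and in union regions, for H3K27me3 (5 WT, 4 DKO) and total H3 (2 WT, 2 DKO); points are libraries and bars the mean and SD. The chromosome 11 share was higher in DKO, including total H3 (9.97% against 8.09%), while the chromosome 6 ranges of H3K27me3 overlap.

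The authors' lists of regions differed most on chromosomes 6 and 11. They held 10898 WT-specific, 28174 shared and 18837 DKO-specific regions, with median lengths of 417, 1334 and 451 bp. Chromosome 6 held 7698 (70.6%) of the WT-specific, 10698 (38.0%) of the shared and 5653 (30.01%) of the DKO-specific regions. Chromosome 11 held 65 (0.6%) of the WT-specific and 2341 (12.4%) of the DKO-specific regions. A promoter row was overlapped by at least 1 bp by 10.2% of WT-specific, 34.8% of shared and 13.9% of DKO-specific regions. The lists carry no replicates, so these numbers have no error and no test.

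**Figure D3:**
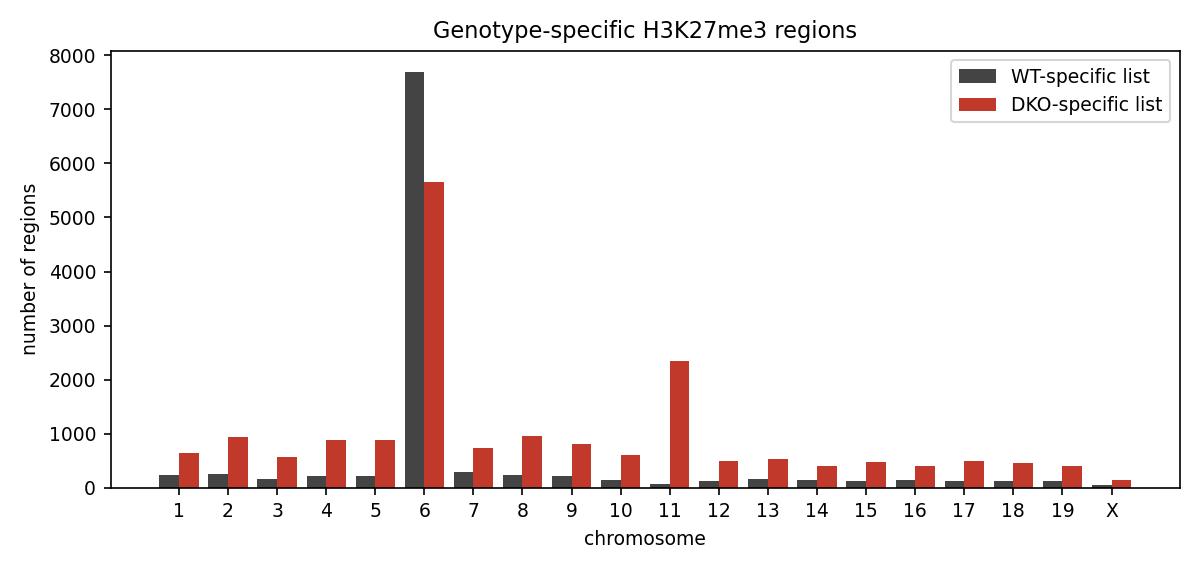
Number of regions (vertical axis) per chromosome (horizontal axis) in the authors' WT-specific and DKO-specific lists, 1 bar per list. Chromosome 6 has 7698 WT-specific and 5653 DKO-specific regions, and chromosome 11 has 65 and 2341.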

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

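The tests of chromosome 11 copies, of the remaining chromosome 11 regions after the offset, of the library sets, of nucleosome content, of enrichment and of the level trend were chosen after the result was seen, as were the longest regions and chromosome 11 themselves, while the tests of the splits were not, except that of shared regions.

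Libraries far from the others of their group were sought in 116 groups of values, and 3 were found. Chance flags about 1 in 20 groups, so these 3 are no more than chance would give. The Arid3b promoter stood at 7.167 CPM in WT replicate 4, against 19.3 to 22.0 CPM in the other WT libraries, and its log2 fold change was 0.92 and still passed without that library. The B2m promoter stood at 52.56 CPM in WT replicate 4, and its log2 fold change was -0.28 without it. The Itga5 promoter stood at 47.95 CPM in DKO replicate 3, and its log2 fold change was 0.355 without it, against 0.62 with it.

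The higher counts on chromosome 11 were weighed as a change of copy number, as the library sets and as a change of the mark. Total H3 on chromosome 11 had a median log2 fold change of 0.311 against -0.019 off chromosomes 6 and 11. The share of promoter rows without a region was 5.07% in WT and 6.14% in DKO. This share was 5.488% in the clone 4 library and 6.247% to 6.512% in the clone 13 libraries, against 4.96% to 5.22% in WT. Both DKO libraries of total H3 came from clone 13. More copies of chromosome 11 in clone 13 cells would give both results. For clone 4 the rise was smaller and total H3 was not measured. With the chromosome 11 offset, 1.14% of its tested regions were higher against 0.983% off chromosomes 6 and 11, where its shared regions held 11 higher and 34 lower of 1418 (0.776% and 2.40%, against 0.533% and 2.24%) and its DKO-specific regions, whose rise selection favours, 20 higher and 0 lower of 1281 (1.56% higher, against 2.62%). The difference in the share of rows without a region was 0.896 points within the libraries without Old or New in the label and 1.28 points within those with it, which argues against the library sets as the cause. Copy number was not measured, total H3 has only 2 libraries a genotype, and whether a gain arose in the clones or followed the loss of SAFB stays open and untested.

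The lower H3K27me3 of the longest shared regions was weighed as nucleosome content, enrichment of the libraries and signal level. Total H3 at the same 91 regions had a median of -0.0300 (quartiles -0.0937 and 0.0308), against -0.29 for H3K27me3, which argues against fewer nucleosomes. With the level offset, 69 of the 91 regions had a match in level among regions of 5 to 20 kb. They differed from their matches by a median of 0.0215 (quartiles -0.0707 and 0.132). A trend with signal level alone would give this. The offset was fitted to the same rows and also removes a real change that grows with level, so the 2 cannot be told apart. The unmatched regions were not compared. The share of promoter counts on rows with a region off chromosomes 6 and 11 was 51.2 ± 2.78% (SD, n = 5) in WT and 51.7 ± 2.00% (SD, n = 4) in DKO, a difference of 0.495 points (exact permutation test, p = 0.818), and less enriched DKO libraries cannot be told apart from equal ones at this spread. Whether such a trend reflects the libraries or a change at the strongest Polycomb targets stays open.

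Other splits of the 9 H3K27me3 libraries into groups of 5 and 4 gave fewer calls for promoters and regions, in 60 of 126 possible splits drawn. Only the true split (1 of 60) gave as many as 205 promoters (highest other 8), 1173 WT-called regions (highest other 63) or 1372 DKO-called regions (highest other 50). Regions called in 1 genotype were selected by the true split, which favours it in the region counts. Among shared regions alone 1 of 60 splits, the true one, gave as many as 915 calls (highest other 40). For promoters and shared regions the true split thus gave more calls than any other drawn. Every other split mixes WT and DKO libraries, so a difference between them adds to the spread within its groups and can lower its calls. All DKO libraries except replicate 1 came from clone 13, so the splits cannot tell genotype from a trait of that clone. For the gene lists, 15 of 60 splits gave at least 4 calls (highest other 6), so a random grouping is not excluded.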

How the results depend on the processing

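The tests with offsets, on rows scaled over all rows, with WT libraries of 1 name stem, within libraries with or without Old or New in the label, off chromosome 11, with scaling off chromosomes 6 and 11, on 1 set of called regions, by fry, relative to total H3 and of shares in union regions or with another denominator were chosen after the result was seen. Of the named promoters under alternatives, 896 of 1103 values kept their direction and side of the threshold, 171 lost a call, 32 gained one and 4 changed sign. For named regions 419 of 467 values did so, 40 lost a call, 1 gained one and 7 changed sign. For total H3 regions 17 of 36 did so and 19 lost a call. The chromosome 6 share was lower in DKO under each alternative run (adjusted p from 0.191 to 0.889). Small changes are mostly missed, since 11.9% of simulated 1.5-fold changes at promoters were recovered. With WT replicates 1, 4 and 5 as the only WT libraries, and so 7 libraries in all, there were 90 promoters, 621 WT-called and 772 DKO-called regions and 3 lists, of which 80, 563, 691 and 3 were also called with all libraries, and 60 of the 91 longest regions fell. Single genes and regions were not tested this way. A planned selection of regions by score was not run, since the lists hold no score.

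The count of 205 promoters became 134 with no filter, where more rows were tested, 398 (190 rises, 208 falls) with a strict filter and 500 (224 and 276) over rows with a region, both of which also rescale the libraries. With the scaling over all rows kept these were 250 (132 and 118) and 332 (227 and 105), so part of the increase and the turn of the balance came from the scaling, and the rest was not traced further. With all rows it was 389 with a library set term, and the cause was not tested. It was 78 off chromosome 11, 100 with the chromosome 11 offset and 100 with both offsets. Of the 205, 84 lay on chromosome 11, against 11 with either offset fit, so most of the drop came from its rows. The 121 calls elsewhere became 78, 89 and 89. The adjustment runs over all tested rows, so calls elsewhere depend on the chromosome 11 rows too. Elsewhere 2665 rows had an unadjusted edgeR p under 0.05 with all rows, against 2643 in the fit without chromosome 11. How much of the change elsewhere came from the adjustment was not tested. With fewer libraries it was 22 without and 57 with Old or New in the label, and 50 to 253 without 1 library each.

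The 1173 WT-called regions became 657 by DESeq2, 719 with the chromosome 11 offset, 136 without and 498 with Old or New in the label, 1 relative to total H3 and 481 to 2192 without 1 library each. The 1372 DKO-called regions became 715, 718, 141, 611, 1 and 558 to 2301 in the same order. With the chromosome 11 offset, calls on chromosome 11 went from 293 to 45 and from 538 to 65, and calls elsewhere from 880 to 674 and from 834 to 653. The cause was not tested beyond this and the smaller number of libraries. The 4 regions of total H3 became 0 by DESeq2 (157 at an unadjusted p under 0.05, 1169 by edgeR), 2 with no filter and 0 to 4 without 1 library each. The 4 gene lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (4), and 3 to 5 without 1 library each. The share of regions that overlap a promoter row was 23.4%, against 8.05% where 50% of a row had to be covered and 41.6% for regions of at least 1000 bp.

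Signs changed for few items, and the cause was not tested. Thoc1 ran from -0.27 to 0.034 without 1 library each, Hoxb1 was -0.063 with the chromosome 11 offset and Hoxc4 was 0.034 in libraries with Old or New in the label. With the level offset the HoxA region was 0.0046, the HoxC region 0.022 and the HoxB region 0.35. The HoxB region was 0.040 by library totals, 0.0395 in libraries with Old or New in the label, 0.045 in the fit to WT-called regions and -0.051 to 0.0049 without 1 library each.

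Replicate numbers do not pair the libraries. Same-numbered libraries correlated between -0.00867 and 0.0337 over promoters and between -0.0278 and 0.0714 over regions, and 0 of 4 DKO libraries correlated best with its own number. Over promoters DKO replicate 3 correlated best with WT replicate 4 (both Old, 0.065) and DKO replicate 4 with WT replicate 5 (both New, 0.0436). Over regions these pairs stood at 0.00612 and 0.0906, and DKO replicate 3 correlated best with WT replicate 1 (0.0216). With the replicate block the counts were 109 promoters, 775 WT-called regions, 847 DKO-called regions, 5 total H3 regions and 6 lists, which added pluripotency genes, lower (adjusted p of 0.0437), and the SAFB and nuclear speckle list, higher (adjusted p of 0.0496), and the chromosome 6 difference was -0.24 points.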

Other observations

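The tests of the ERK gene set and of the level trend, and the genes and regions below, were chosen after the result was seen.

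Of 12 tested promoters on a list of ERK feedback and early response genes, 4 rose: those of Spry2, Dusp6 and Etv5, which prompted the list, and that of Dusp4. The others did not pass, and ran from Il17rd at 1.05 to Ier3 at -0.27. Etv5, a transcription factor induced by ERK signalling, rose by 0.95 on the log2 scale, from 30.8 ± 6.16 CPM (SD, n = 5) to 58.0 ± 3.48 CPM (SD, n = 4), with all 4 DKO libraries above every WT library. It stood at 0.71 (not passing) and 1.28 within the libraries without and with Old or New in the label. Dusp4, an ERK phosphatase, rose by 0.51, a call that ended without WT replicate 4 or 5 or DKO replicate 2 or 4 (0.41 to 0.50). The region of Etv4 on chromosome 11 (101779762 to 101785058) stood at 1.285 and passed, while total H3 there stood at 0.92 and did not. Relative to total H3 it was 0.34 and did not pass. The H3K27me3 value was 0.96 and 1.80 within the libraries without and with Old or New in the label, both passing. The region of Spry4 on chromosome 18 (38598844 to 38601165) rose by 1.15, with 3 of 4 DKO libraries above every WT library, and stood at 0.81 (not passing) and 1.57 within the libraries without and with Old or New in the label, while total H3 there stood at 0.30 and did not pass. The WT-specific region of Klf2 on chromosome 8 (72319584 to 72321040) fell by 1.51, at -1.76 and -1.22 within these sets, both passing.

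A hypothesis from these values is that ERK feedback and early response genes gained H3K27me3 as a group. After Spry2, Dusp6 and Etv5 had been seen, 13 other genes were chosen by function, of which 7 could be tested: Dusp4, Dusp5, Egr1, Fos, Ier3, Myc and Phlda1. Of these 1 rose, Dusp4, and 6 values were positive and 1 negative, with a median of 0.41 (camera with an estimated correlation, p = 0.00539). The set was redefined after a first test of another subset, with 8 tested genes, had given a camera p of 0.0114, so the smaller p came second. The camera p of the 7 genes was 0.00335 with the chromosome 11 offset, and with 2 genes added later it was 0.00626 without that offset. With the level offset the median of the 7 genes was 0.36 and their camera p 0.00306, which argues against a trend with level alone. The set was prompted by the same libraries and RNA was not analysed here, so the shift may not hold in other clones.

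The row that spans chromosome Y held 1.19 ± 0.0849% of promoter counts in WT (SD, n = 5) and 0.949 ± 0.0785% in DKO (SD, n = 4), with an exact permutation p of 0.00794, the smallest these groupings can give. At the CT010467.1 region on chromosome 17 (39842973 to 39848922) H3K27me3 fell by 1.23 and total H3 by 0.50 on the log2 scale. Short shared regions within Lars2 on chromosome 9 (123461787 to 123462262), Cmss1 and Filip1l on chromosome 16 (57391305 to 57391825) and Cdk8 on chromosome 5 (146260825 to 146261349) stood at -1.14, -1.10 and -1.065 and passed, while total H3 at these regions stood at -0.31, -0.40 and -0.42 and did not pass. In WT they held 103, 247 and 105 CPM over 476, 521 and 525 bp. Whether reads from other copies of a sequence were placed at these regions was not tested, so a change particular to these genes is not shown.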
